A study of Homo sapiens with 6 samples.

How the data were processed

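RNA was sequenced from RMS13 cells, an established human rhabdomyosarcoma line, 72 h after transfection with a small interfering RNA (siRNA) against GLI1 (group siGLI1) or, per the labels, a non-targeting siRNA (group siNT2). Each group had 3 libraries, numbered replicates 1, 2 and 3 in the sample titles. Cells were grown in RPMI with fetal bovine serum, total RNA was purified on columns with a DNase step, and libraries were made with an Illumina mRNA kit, per the labels' protocols. The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

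The submitters' processing notes name bcl2fastq, Trim Galore 0.4.5, Bowtie2 2.3.3.1, featureCounts from Subread 1.6.4, DESeq2 2.11.40.6 and the genome build hg19. Whether the reads were counted with strand, how reads matching several places were handled, and which gene annotation was used are not given in the sources used here. Genes that overlap, lie antisense to each other or belong to families of near-identical copies therefore carry an uncertainty in their values. Bowtie2 does not split reads across introns, so a read that spans a junction between exons can be lost, which lowers counts of genes with many short exons in both groups alike.

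The authors deposited a single table of signal values, read counts per gene divided by 1 size factor per library, with no division by gene length. In each column 100.0% of the values were whole multiples of what 1 read is worth, within a tolerance of 0.01 reads, so whole reads were recovered. They summed to 13673977, 15498340 and 18947614 in the siNT2 libraries and 13784642, 14312681 and 15477041 in the siGLI1 libraries. A count of 0 allows up to 3 reads, which is 2.39 to 3.29 in deposited units. This floor covers counting error only, since reads amplified by PCR are not independent molecules. No pair of libraries in a group agreed within sampling noise, so all 6 were kept as separate samples.

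The table listed 25702 genes by Entrez gene number. Symbols came from a RefSeq gene table of assembly GRCh38.p14, which gave a symbol to 23696 of the IDs (92.2%) and none to 2006. Because that assembly differs from hg19, it was used for names, gene order and overlap, and no coordinates are printed. GC content, transcript length and 3' untranslated region (3' UTR) sequences came from GENCODE release 29 transcripts. Of the genes tested, 14438 (92.4%) had a GC value.

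Analyses ran in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The main test was limma 3.58.1 (lmFit, then eBayes with a mean-variance trend) on log2 of the deposited value plus a pseudocount of 1, with the group as the only term. Genes with a mean deposited value of 10 or more over the 6 libraries entered the test, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, siGLI1 minus siNT2, which understates the change of low genes. Intervals are 95% confidence intervals from the same model. The design was fixed before the data were examined. The count tests edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0, run on the recovered whole reads, were alternatives. edgeR called 1182 genes higher and 1200 lower, and 2320 genes were called by both edgeR and limma.

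Named genes followed a rule set before the data were examined. It took GLI1, 13 core Hedgehog genes, and the 12 largest increases and 12 largest decreases among genes with an adjusted p under 0.05, a mean of 50 or more and no overlap between the groups. It also took up to 4 members of each gene list with the smallest p-values. Some genes that the rule took are not reported here. A gene named outside the rule is said to be so where it appears. The 25 lists, also fixed beforehand, were Hedgehog pathway components, textbook GLI target genes, 12q13-q15 neighbours of GLI1, PAX3-FOXO1 associated genes, myogenic regulators, muscle contractile differentiation genes, G1/S and DNA replication genes, G2/M and mitosis genes, p53 pathway and cell cycle inhibitors, apoptosis regulators, interferon-stimulated genes, unfolded protein and amino acid stress genes, cholesterol biosynthesis genes, MAPK and FGF feedback genes, WNT, Notch, and TGF-beta and BMP pathway genes, extracellular matrix and mesenchymal genes, hypoxia and glycolysis genes, epithelial, blood cell and neural markers, replication-dependent histone genes, cytosolic ribosomal protein genes, and oxidative phosphorylation genes. GLI1 itself was taken out of every list. Lists were tested with camera at a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 25 lists. The alternatives were camera with an estimated correlation and fry. Some genes sit in more than 1 list.

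The scripts were tested on simulated counts drawn for the real genes at the real depths. Each gene was drawn independently, with 1 assumed dispersion (spread beyond counting error) of 0.04 for all genes. With 195 genes changed among 15527 tested in the simulated comparison of the 2 groups, limma recovered 62.2% of the 98 genes changed by a fold of 2 and 100% of the 97 changed by a fold of 4, with 9 false calls. With a GC trend added to the simulated libraries, recovery at a fold of 2 fell to 3.1%, and rose to 63.3% once the trend was removed. In a simulation of gene lists, a lowered list was called and 0 of 50 unchanged lists were. With genes drawn independently, this cannot show how often lists of correlated genes are called wrongly. In the real libraries the estimated correlation was 0.192 for the muscle contractile list.

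Alternatives were other pseudocounts, filters, scalings and variance models, a replicate block, count tests, stricter thresholds, and leaving out each library in turn. Alternatives chosen after seeing the data were a GC correction (a loess trend, span 0.3, of each library's deviation from the gene mean on GC content), the same correction with a replicate block, leaving out 2 libraries at one end of the GC trend, and leaving out genes with a heptamer in the 3' UTR. Genes linked to the Y chromosome and XIST were left out of all named genes. Raw reads and the siRNA sequences were not used here.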

Results

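Gene expression was measured by RNA sequencing in 6 libraries of RMS13 cells, a human line of rhabdomyosarcoma, a tumour with features of skeletal muscle. GLI1 encodes a zinc finger transcription factor that acts at the end of the Hedgehog signalling pathway. The comparison asked how expression responds when GLI1 is lowered by siRNA. There were 3 libraries from cells transfected with the GLI1 siRNA (siGLI1) and 3 from cells with a non-targeting siRNA (siNT2), all taken at 72 h. Recovered reads ranged from 13673977 to 18947614 per library, and 19355 to 20292 genes were detected. Values below are normalised read counts as mean ± SD, and fold changes are siGLI1 minus siNT2 on the log2(value + 1) scale. Adjusted p-values are from limma with Benjamini-Hochberg adjustment unless another test is named.

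GLI1 itself (Entrez gene 2735) was lower in every siGLI1 library than in any siNT2 library. Its normalised read count was 11962.5, 17836.9 and 12774.1 in the siNT2 libraries and 579.9, 905.8 and 1274.1 in the siGLI1 libraries. The siGLI1 mean of 919.9 ± 347 (SD, n = 3) was 6.48% of the siNT2 mean of 14190 ± 3180 (SD, n = 3). GLI1 fell by 4.00 on the log2 scale (standard error 0.29, 95% interval -4.67 to -3.32, adjusted p = 0.000425). In siNT2 cells GLI1 ranked 66 by mean count among the genes tested.

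Of 15622 genes tested, 1127 were higher and 1249 lower in siGLI1 cells, together 15.2% of the genes. Of these, 610 rose and 607 fell by a fold of 2 or more. The groups did not overlap in 5659 genes, 36.2% of those tested, against 10% given by chance for 3 against 3 libraries, and all 2376 called genes were among them. The median log2 fold change of all tested genes was -0.01. The first principal component (61.8% of variance) placed the siNT2 libraries below 0 and the siGLI1 libraries above 0, while the second (26.2%) ran across libraries of both groups. Libraries of the same group also differed along GC content. The rank correlation, across genes, between GC content and a library's deviation from its group ranged from -0.59 to 0.69 in siNT2 and from -0.69 to 0.74 in siGLI1, and that of the log2 fold change with GC content was -0.29. Removing this trend left 2308 of the 2376 calls (97.1%) and raised the totals to 2431 higher and 2434 lower. The counts were 425 higher and 450 lower without siNT2 replicate 1, 765 and 806 without siNT2 replicate 2, 648 and 683 without siNT2 replicate 3, 708 and 799 without siGLI1 replicate 1, 280 and 359 without siGLI1 replicate 2, and 1543 and 1704 without siGLI1 replicate 3. Of the 25 gene lists, camera called 4 higher and 2 lower, and 0 with an estimated correlation, where 4 lists had an unadjusted p under 0.05. The 3' UTR was annotated for 13072 tested genes, of which 1257 carried the heptamer GCACCTC. Of genes with 1 copy 17.2% were called lower, of genes with 2 or more copies 22.7%, and of genes without it 7.1%.

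**Figure D1:**
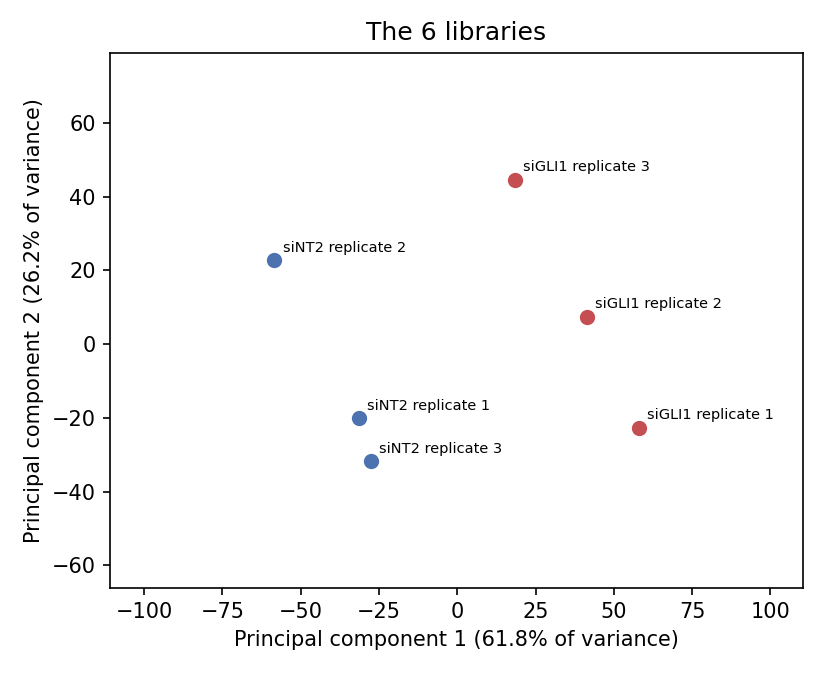
Principal components of the 6 libraries from log2 normalised read counts of the tested genes, with the share of variance on each axis. Each point is 1 library, coloured by group. The siNT2 libraries lie between -58.4 and -27.7 on the first component and the siGLI1 libraries between 18.4 and 57.9.

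Direct readouts of Hedgehog signalling were lower after the knockdown. PTCH1, which encodes a Hedgehog receptor and is induced by the pathway, and HHIP, which encodes a ligand-binding feedback inhibitor, were lower in all 3 siGLI1 libraries than in any siNT2 library. PTCH1 went from 2611 ± 341 to 556.2 ± 39.3 (SD, n = 3 per group), a log2 fold change of -2.22 (standard error 0.14, adjusted p = 0.000277). HHIP fell by 1.79 (adjusted p = 0.000596). The forkhead gene FOXF1 fell by 1.09 (adjusted p = 0.00693) and the cyclin gene CCND1 by 0.55 (adjusted p = 0.0283), though the CCND1 call was lost in 5 of the 6 fits that left out 1 library. FOXF1 carried 1 copy of the heptamer GCACCTC in its 3' UTR.

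The other core genes did not pass the test. GLI2, a second GLI family activator, had a log2 fold change of -0.49 (95% interval -0.82 to -0.16, adjusted p = 0.0557 with limma and 0.0583 with edgeR), and SMO, the pathway's membrane transducer, one of -0.59 (adjusted p = 0.109). DESeq2 called GLI2 lower (adjusted p = 0.0246), as limma did without siGLI1 replicate 3 (adjusted p = 0.0403), while with the GC correction GLI2 was at -0.28 (adjusted p = 0.114). With the GC correction SMO reached -0.37 at an adjusted p of 0.00978, with limma. The values were 0.10 for GLI3, 0.17 for SUFU, -0.44 for BCL2, 0.03 for MYCN, -0.12 for CCND2 and 0.16 for SFRP1, with adjusted p-values from 0.219 (BCL2) to 0.944 (MYCN). SUFU was called higher once the GC trend was removed (0.32, adjusted p = 0.0301, limma). MYCN and SFRP1 changed sign when single libraries were left out.

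**Figure D2:**
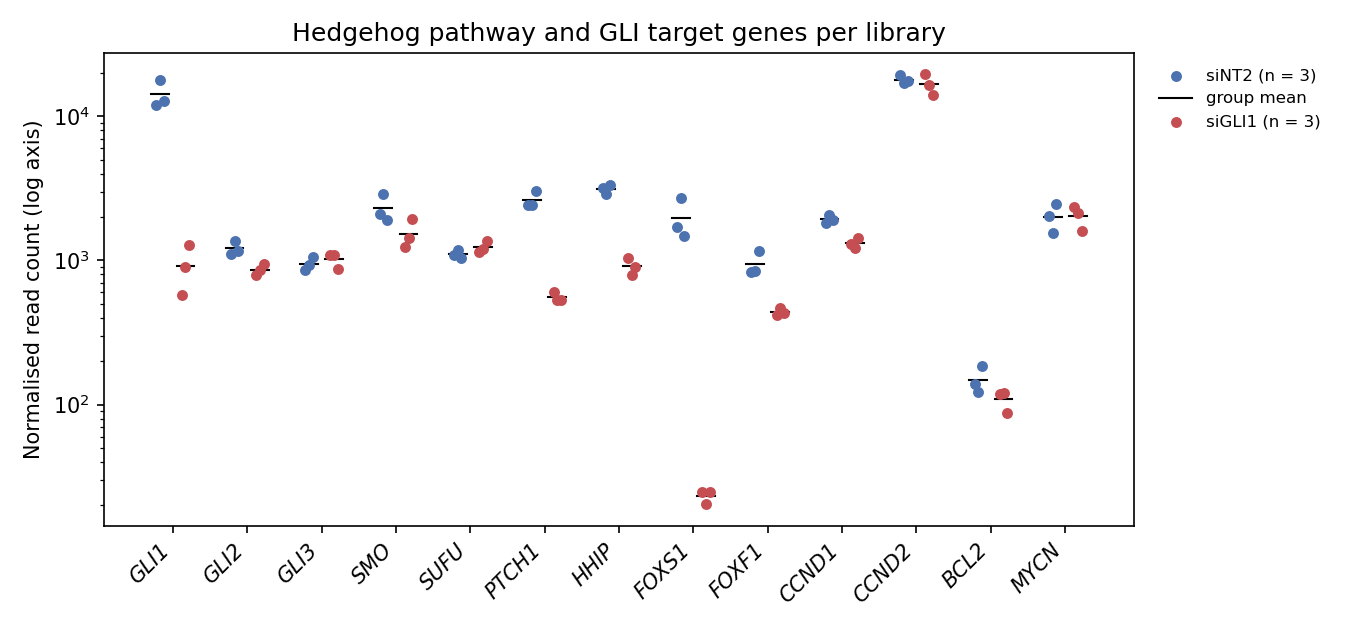
Normalised read count (log axis) of Hedgehog pathway genes and GLI targets in each library, 3 per group, with black lines for group means. GLI1, PTCH1, HHIP and FOXS1 lie lower in all siGLI1 libraries, with FOXS1 at 20.4 to 24.8 against 1473.7 to 2726.2.

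Among 35 measured textbook GLI target genes, 10 fell and 3 rose, and 22 were not called. Adjusted over the list alone, 12 fell and 3 rose. The median log2 fold change was -0.39, and camera called the list lower (adjusted p = 0.00151), a call not made with an estimated correlation (adjusted p = 0.209). The largest decrease in the list was the forkhead gene FOXS1, which went from 1964 ± 669 to 23.33 ± 2.49 (SD, n = 3 per group), a log2 fold change of -6.29 (adjusted p = 9e-05). CFLAR, an inhibitor of caspase 8 activation, fell by 1.81 (adjusted p = 0.00108) and carried the GCACCTC heptamer in its 3' UTR. The 3 that rose were TNC, HSD11B2 and SNAI1, named after their values were seen, with log2 fold changes of 1.13, 1.33 and 0.81. Of 21 Hedgehog pathway components, 4 fell and 4 rose, and 5 fell and 4 rose adjusted over the list alone. Their median was -0.18, and camera gave an adjusted p of 0.301. The median was above 0 with the GC correction (0.02), without siGLI1 replicate 1 (0.02), with no filter on low values (0.04) and with library weights (0.009). Besides the decreases in PTCH1 and HHIP, the ligand release gene DISP1 was higher (0.74, adjusted p = 0.0217), a call lost without any of 4 single libraries.

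The 12 largest decreases included genes for an integrin, a matrix protease and a lactate transporter, besides GLI1 and FOXS1. ITGB3, the integrin beta 3 subunit, went from 973.4 ± 124 to 44.4 ± 6.49 (SD, n = 3 per group), a log2 fold change of -4.43 (adjusted p = 9e-05). MMP15, a membrane-bound matrix metalloproteinase, fell by 4.72 (adjusted p = 0.000277), and both genes carried 1 GCACCTC heptamer in the 3' UTR. The NMDA receptor subunit gene GRIN1 had a log2 fold change of -4.76 (adjusted p = 0.000629), and SLC16A3, which encodes a lactate transporter, one of -3.69 (adjusted p = 0.000353). MAG, the myelin-associated glycoprotein gene, went from 134.3 ± 21.5 to 1.69 ± 1.1 and the germ cell transcription factor gene SOHLH1 from 110.8 ± 31.3 to 2.02 ± 2.05 (SD, n = 3 per group). Both siGLI1 means were under the floor of 3 reads. Their fitted log2 fold changes of -5.72 and -5.46 therefore depend on the pseudocount, and were -3.87 and -3.55 with a pseudocount of 8. TAGAP, RPRML and LINC00639 were also among the 12 largest decreases, with log2 fold changes of -3.30, -3.29 and -3.23 (adjusted p at most 0.011).

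The 12 largest increases included the skeletal muscle genes MSTN, MYH8, KLHL41, MYOZ2 and CMYA5. DMP1, an extracellular phosphoprotein gene of mineralised tissue, rose from 7.73 ± 1.37 to 218.7 ± 50.7 (SD, n = 3 per group), a log2 fold change of 4.64 (adjusted p = 0.000277). ANKRD1, an ankyrin repeat gene of stressed and developing muscle, rose by 4.19 (adjusted p = 0.000277). The water channel genes AQP1 and AQP3 rose by 3.58 (adjusted p = 0.000245) and 2.87 (adjusted p = 0.000277). MSTN, which encodes the muscle growth inhibitor myostatin, rose from 549.9 ± 248 to 4769 ± 1700 (SD, n = 3 per group; log2 fold change 3.16, adjusted p = 0.00346). The perinatal myosin heavy chain gene MYH8 rose by 3.47, an uncertain value since its reads can be shared with the neighbouring myosin genes that resemble it. The sarcomere-associated genes KLHL41, MYOZ2 and CMYA5 rose by 2.83, 2.78 and 2.62 (adjusted p at most 0.00725). ASB5, CASS4 and DCLK1 rose by 2.85, 2.78 and 2.74 (adjusted p at most 0.00257).

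Genes of muscle contraction rose as a group. Of 43 measured muscle contractile differentiation genes, 18 rose and 2 fell, and 24 rose and 4 fell adjusted over the list alone. The median log2 fold change was 0.78, and camera called the list higher (adjusted p = 5.11e-07), but not with an estimated correlation (adjusted p = 0.447). KLHL41 went from 529.2 ± 114 to 3714 ± 146 (SD, n = 3 per group; adjusted p = 0.000277), and MYPN, a sarcomere Z-disc protein gene, rose by 3.27 (adjusted p = 0.00173). The siNT2 mean of MYPN, 3.57, was close to the floor of 3 reads, so its fold change depends on the pseudocount. The 2 that fell were LDB3, another Z-disc gene, by 1.11 and the calcium pump gene ATP2A1 by 1.37, both named after their values were seen. Of 26 myogenic regulators, 7 rose and 3 fell, with 11 and 3 adjusted over the list alone, a median of 0.48 and an adjusted p of 0.00888 from camera (adjusted p = 0.209 with an estimated correlation). After the GC correction 13 of them were higher. MSTN and the muscle adhesion gene NCAM1 (1.11, adjusted p = 0.00375) rose. HEYL, a transcriptional repressor downstream of Notch with 1 GCACCTC heptamer in its 3' UTR, fell from 4634 ± 171 to 1220 ± 93.1 (SD, n = 3 per group; log2 fold change -1.93, adjusted p = 0.000277).

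**Figure D3:**
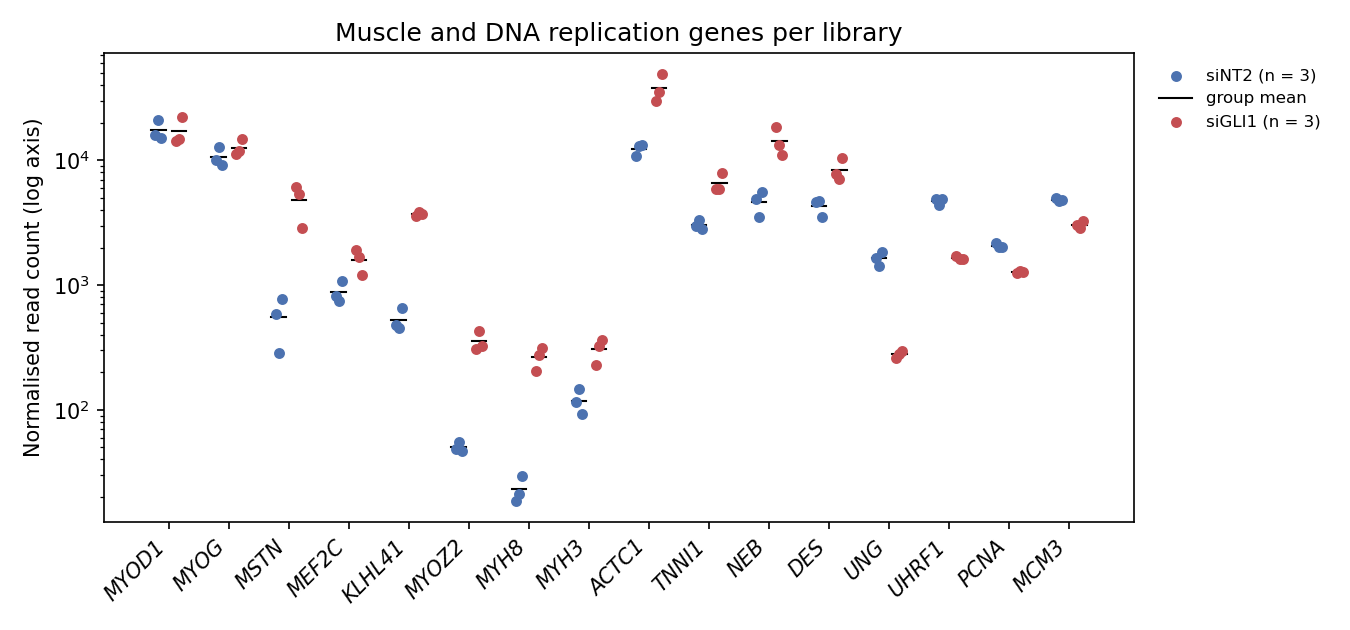
Normalised read count (log axis) of muscle genes and DNA replication genes in each library, 3 per group, with black lines for group means. KLHL41 spans 449.3 to 659.5 in siNT2 and 3554.1 to 3841.9 in siGLI1, and UNG spans 1422.9 to 1850 in siNT2 and 259.2 to 298.3 in siGLI1. The values of MYOD1 and MYOG, named outside the rule, overlap between the groups.

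Genes associated with PAX3-FOXO1, the fusion transcription factor of alveolar rhabdomyosarcoma, were also higher. Of 29 measured, 9 rose and 0 fell, and 11 rose adjusted over the list alone. The median was 0.24 and the camera adjusted p was 0.000608 (adjusted p = 0.289 with an estimated correlation). The chemokine receptor gene CXCR4 went from 1550 ± 54.4 to 3649 ± 18.4 (SD, n = 3 per group; log2 fold change 1.24, adjusted p = 0.000928). DCX, a microtubule-associated protein gene, rose by 1.62 (adjusted p = 0.000514), the adrenergic receptor gene ADRA2A by 1.67 (adjusted p = 0.00167) and RASSF4 by 1.13 (adjusted p = 0.00268).

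Genes for entry into and progress through DNA replication were lower, while mitotic genes were not called as a group. Of 40 G1/S and DNA replication genes, 13 fell and 0 rose, and 20 fell adjusted over the list alone. The median was -0.43, and camera called the list lower (adjusted p = 1.41e-09), though not with an estimated correlation (adjusted p = 0.209). After the GC correction 26 of the 40 were lower. UNG, the uracil-DNA glycosylase gene, went from 1638 ± 214 to 279.2 ± 19.6 (SD, n = 3 per group; log2 fold change -2.54, adjusted p = 0.000277) and carried 1 GCACCTC heptamer in its 3' UTR. UHRF1, which maintains DNA methylation, fell by 1.52 (adjusted p = 0.000514), the checkpoint gene CLSPN by 1.19 (adjusted p = 0.00137) and the ribonucleotide reductase gene RRM2 by 0.77 (adjusted p = 0.00633). Of 43 G2/M and mitosis genes, 1 rose and 0 fell, and the same counts held adjusted over the list alone. Their median was 0.03 against a mean of -0.01, and camera gave an adjusted p of 0.821. The gene that rose was CCNB2 (0.60, adjusted p = 0.0128), whose call was lost without siNT2 replicate 1 or siGLI1 replicate 2, while BIRC5, INCENP and CDC25B had adjusted p-values of 0.0652 to 0.0781. The GC correction gave 2 higher and 8 lower.

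**Figure D4:**
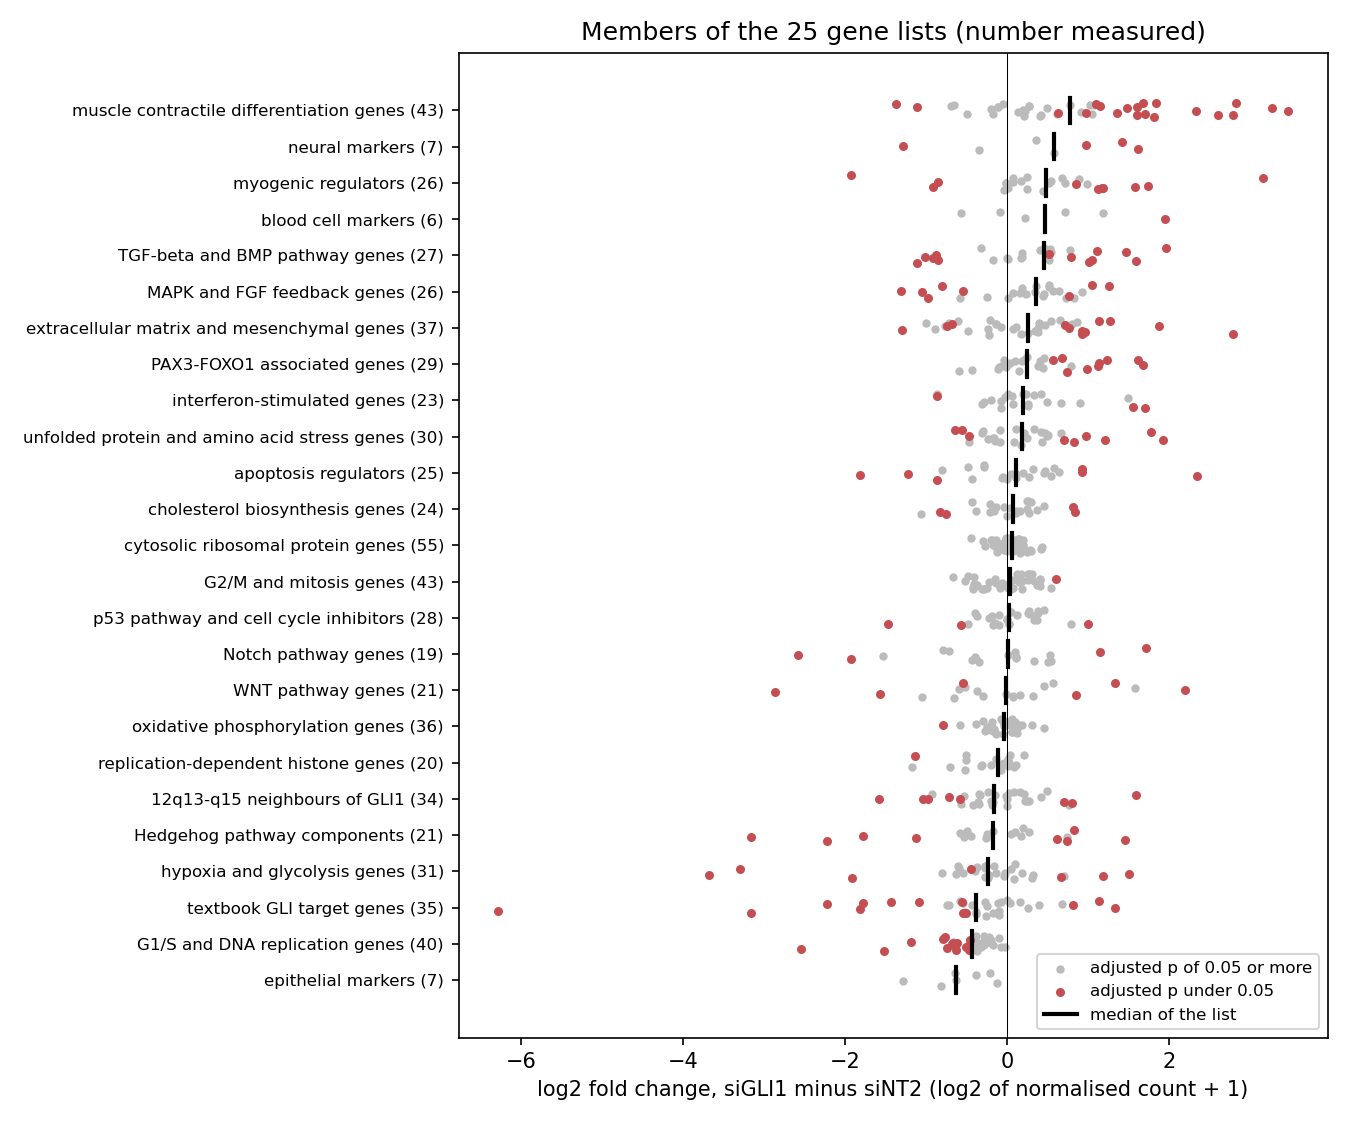
Log2 fold change, siGLI1 minus siNT2, of each measured member of the 25 gene lists, sorted by median. Red points passed an adjusted p of 0.05 over all genes, grey points did not, and black bars are list medians. The muscle contractile list has a median of 0.78 and the G1/S list one of -0.43.

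Signalling lists moved in mixed directions. Of 27 TGF-beta and BMP pathway genes, 8 rose and 5 fell, with 9 and 5 adjusted over the list alone and a median of 0.46. The camera call (adjusted p = 0.0422) was not made with an estimated correlation (adjusted p = 0.482) and held in 2 of the 6 fits that left out 1 library. INHBE rose by 1.59 (adjusted p = 0.00127), the ligand gene TGFB3 by 1.47 (adjusted p = 0.00209) and the BMP antagonist gene NOG by 1.11 (adjusted p = 0.00348). Of 21 WNT pathway genes, 3 rose and 3 fell (4 and 4 adjusted over the list alone, median -0.01, or 0.05 with the GC correction, camera adjusted p = 0.701). The ligand gene WNT11 fell by 2.86 (adjusted p = 0.000277) and the receptor gene FZD8 by 1.57 (adjusted p = 0.000544), while the secreted antagonist gene SFRP4 rose by 2.20 (adjusted p = 0.000474) and DKK3 by 0.85 (adjusted p = 0.0162), the last a call lost without siNT2 replicate 1 or siGLI1 replicate 2. Of 19 Notch pathway genes, 2 rose and 2 fell (3 and 3 adjusted over the list alone), and the median of 0.003 and the mean of -0.215 differed in sign (camera adjusted p = 0.675). The ligand gene DLL1 rose by 1.15 (adjusted p = 0.00178) and MFNG by 1.71 (adjusted p = 0.0207), and HEYL and NRARP (-2.59, adjusted p = 0.00807) fell. The siGLI1 mean of NRARP, 3.04, was close to the floor of 3 reads, so its fold change depends on the pseudocount. The MFNG call was lost without siNT2 replicate 3 or siGLI1 replicate 2.

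Of 26 MAPK and FGF feedback genes, 3 rose and 5 fell, with 6 and 5 adjusted over the list alone, a median of 0.35 and a camera adjusted p of 0.251. After the GC correction 12 rose and 5 fell. ETV4 (-1.32, adjusted p = 0.00257), ETV5 (-1.05, adjusted p = 0.0159) and DUSP5 (-0.98, adjusted p = 0.00887) fell, and EGR2 rose by 1.25 (adjusted p = 0.0108). ETV5 and DUSP5 carried the GCACCTC heptamer. When 1 library was left out, the ETV5 call was lost in 3 of the 6 fits, that of EGR2 in 2 and that of DUSP5 in 1. Of 37 extracellular matrix and mesenchymal genes, 9 rose and 3 fell (12 and 6 adjusted over the list alone, median 0.26, camera adjusted p = 0.164, a list called higher without siNT2 replicate 3). The elastic fibre gene FBLN5 went from 335.6 ± 9.7 to 811 ± 6.85 (SD, n = 3 per group; log2 fold change 1.27, adjusted p = 0.00127). CNN1 rose by 1.88 (adjusted p = 0.00453) and COL1A2 by 2.79 (adjusted p = 0.00593), the latter from a mean of 4.43, and LAMB1 fell by 0.68 (adjusted p = 0.00825), a call lost without siNT2 replicate 1 or siGLI1 replicate 2.

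Genes of cell death and stress included single large changes. Of 25 apoptosis regulators, 3 rose and 3 fell (5 and 4 adjusted over the list alone, median 0.10, camera adjusted p = 0.675), and the median was -0.04 without siNT2 replicate 2. The pro-apoptotic gene BMF went from 315.3 ± 41 to 1617 ± 351 (SD, n = 3 per group; log2 fold change 2.34, adjusted p = 0.000773), CASP9 rose by 0.92 (adjusted p = 0.00453) and BCL2L11 by 0.92 (adjusted p = 0.0103), the last a call lost without siGLI1 replicate 2. Of 28 genes of the p53 pathway and cell cycle inhibitors, 1 rose and 2 fell, and 1 rose and 0 fell adjusted over the list alone (median 0.02, camera adjusted p = 0.797). The GC correction gave 4 higher and 2 lower, and the median was below 0 without siNT2 replicate 1 (-0.02) or siNT2 replicate 2 (-0.003). GADD45A rose from 1431 ± 171 to 2850 ± 54.8 (SD, n = 3 per group; adjusted p = 0.00373). FDXR, which carried the GCACCTC heptamer, and CDKN2D fell by 1.48 and 0.58 (adjusted p = 0.0322 and 0.0486), calls lost in 5 of the 6 fits that left out 1 library, and CDKN1A had a log2 fold change of -0.40 (adjusted p = 0.083). Of 30 unfolded protein and amino acid stress genes, 6 rose and 3 fell (6 and 4 adjusted over the list alone, median 0.19, camera adjusted p = 0.155), and 12 rose after the GC correction. The stress transcription factor gene ATF3 rose by 1.78 (adjusted p = 0.000548), VLDLR by 1.93 (adjusted p = 0.00348), PPP1R15A by 1.21 (adjusted p = 0.00588) and TRIB3, which carried the GCACCTC heptamer, by 0.97 (adjusted p = 0.00422). Of 23 interferon-stimulated genes, 2 rose and 1 fell, also adjusted over the list alone (median 0.19, camera adjusted p = 0.273). USP18 rose by 1.70 (adjusted p = 0.00205) and ISG20 by 1.55 (adjusted p = 0.0358), HERC6 fell by 0.87 (adjusted p = 0.0273), and EIF2AK2 was not called (0.67, adjusted p = 0.0981). The ISG20 and HERC6 calls were lost in 5 of the 6 fits that left out 1 library.

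Metabolic lists were not called as groups by camera, though fry called the hypoxia and glycolysis list (adjusted p = 0.00187). Of 31 hypoxia and glycolysis genes, 3 rose and 4 fell (3 and 6 adjusted over the list alone, median -0.24, camera adjusted p = 0.164). The pyruvate kinase gene PKM, which carried the GCACCTC heptamer, fell from 26530 ± 1270 to 7048 ± 1020 (SD, n = 3 per group; log2 fold change -1.92, adjusted p = 0.000383), P4HA2 rose by 1.18 (adjusted p = 0.00237), and EGLN3, which also carried it, rose from 278.1 ± 61.2 to 783 ± 113 (SD, n = 3 per group; adjusted p = 0.00386). Of 24 cholesterol biosynthesis genes, MSMO1 and SC5D rose by 0.81 and 0.84 and LSS and EBP fell by 0.83 and 0.76, with the same counts adjusted over the list alone. When 1 library was left out, the SC5D and EBP calls were lost in 5 of the 6 fits, that of MSMO1 in 3 and that of LSS in 2. The list's median was 0.08, its mean -0.003 and its camera adjusted p 0.675. Of 36 oxidative phosphorylation genes, UQCRC1 fell by 0.80 (adjusted p = 0.0112) and was the only member called, also adjusted over the list alone (median -0.04, camera adjusted p = 0.701), a call of UQCRC1 that was lost without siNT2 replicate 1 or siGLI1 replicate 2. Mitochondrially encoded genes took 6.17 to 7.21% of reads in siNT2 libraries and 4.43 to 5.39% in siGLI1 libraries.

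Of the markers written for other cell types, 7 of 20 epithelial, 6 of 22 blood cell and 7 of 21 neural genes were measured. Of the 7 epithelial markers limma called 0, also adjusted over the list alone, 2 had an unadjusted p under 0.05 and edgeR called 0 (median -0.64, camera adjusted p = 0.155). The smallest adjusted p-values there were 0.088 for ELF3 and 0.0994 for EPCAM. Of 6 blood cell markers, ITGAM rose by 1.95 (adjusted p = 0.0189) and 5 were not called, also adjusted over the list alone (median 0.46, camera adjusted p = 0.273). The ITGAM call was lost without siNT2 replicate 1 or siGLI1 replicate 2. Of 7 neural markers, DCX, INSM1 (1.41, adjusted p = 0.01) and MAP2 (0.97, adjusted p = 0.0315) rose and CHGA fell by 1.28 (adjusted p = 0.0131), also adjusted over the list alone (median 0.58, camera adjusted p = 0.164). The MAP2 call was lost in 5 of the 6 fits that left out 1 library, and those of INSM1 and CHGA without siGLI1 replicate 2. Of 20 replication-dependent histone genes, H4C8 fell by 1.15 (adjusted p = 0.0267) and 0 rose, with 0 called adjusted over the list alone (median -0.11, camera adjusted p = 0.273), and the median was 0.07 without siNT2 replicate 1. The list was called lower without siNT2 replicate 3. The H4C8 call was lost in 3 of the 6 fits that left out 1 library. Of 55 cytosolic ribosomal protein genes, whose reads can be shared with pseudogenes, limma called 0, also adjusted over the list alone, 1 had an unadjusted p under 0.05, edgeR called 0 and DESeq2 1. Their median was 0.05, which turned negative without siNT2 replicate 3 or siGLI1 replicate 3 and with library weights, the camera adjusted p was 0.52 (called higher without siNT2 replicate 2), and RPL15 had the smallest adjusted p (0.0532). Of 34 genes near GLI1 in 12q13-q15, 3 rose and 5 fell, also adjusted over the list alone (median -0.17, camera adjusted p = 0.446), and 9 rose and 7 fell after the GC correction. INHBE rose, and B4GALNT1 fell by 1.58 (adjusted p = 0.00217), PIP4K2C by 1.04 (adjusted p = 0.00279) and NAB2 by 0.98 (adjusted p = 0.00532), with PIP4K2C carrying the GCACCTC heptamer.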

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

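Of the settings below, the GC correction, alone and with a replicate block, leaving out 2 libraries at one end of the GC trend, and leaving out genes with the GCACCTC heptamer were chosen after the data were seen. The fall in GLI1 was called under every setting run, with a log2 fold change between -4.27 and -3.70 when 1 library was left out. The pseudocount, the filter on low values, TMM, upper quartile and quantile scaling, eBayes without a trend, edgeR, DESeq2 and leaving out heptamer genes kept both counts of called genes within 1.5 times of 1127 higher and 1249 lower. Library weights raised them to 6209 higher and 6410 lower, with siNT2 replicate 1 weighted 70.4 and siNT2 replicate 2 at 0.143, and the weight estimation stopped before convergence, so these counts rest mainly on few libraries. Requiring a fold of 2 or more gave 610 and 607 by construction, and an adjusted p under 0.01 gave 334 and 406. The GC correction raised the counts to 2431 and 2434, and leaving out siNT2 replicate 2 and siGLI1 replicate 3, the libraries with the most positive GC trend, to 2230 and 2340. Leaving out 1 library gave 280 to 1543 genes higher and 359 to 1704 lower. The libraries whose loss moved a count by over 1.5 times were siNT2 replicate 1 (425 and 450), siNT2 replicate 2 (806 lower), siNT2 replicate 3 (648 and 683), siGLI1 replicate 1 (708 and 799) and siGLI1 replicate 2 (280 and 359). Beyond fewer samples, the cause was not tested.

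With the replicate number as a block, 462 genes were higher and 508 lower, and 1887 and 1892 with the GC correction added. The deviations of libraries with the same number had correlations of 0.49, -0.11 and -0.61, and the numbers were not taken as a pairing. These deviations ran along GC content, with rank correlations from -0.69 (siGLI1 replicate 1) to 0.74 (siGLI1 replicate 3). The GC trend could hide a pairing, so the check cannot exclude one. The labels' library codes share their middle part between libraries of the same number, with no meaning given, so a shared run or day stays open. Under the block the TGF-beta and BMP list was no longer called (adjusted p = 0.064), and the other 5 list calls held. It also ended the calls of 20 singled-out genes, all among those named below as lost when 1 library was left out.

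The lists called higher numbered 3 to 5 and those called lower 2 to 3 when 1 library was left out. Ribosomal protein genes gained a call as higher without siNT2 replicate 2 (adjusted p = 0.00694), and without siNT2 replicate 3 matrix genes did as higher (0.0283) and histone genes as lower (0.0332). With an estimated correlation camera called 0 higher and 0 lower, with 4 lists at an unadjusted p under 0.05, and fry, which does not compare a list with other genes, called 7 higher and 4 lower. The TGF-beta and BMP list lost its call without siNT2 replicate 1 or 2, without siGLI1 replicate 2 or 3, at a mean of 50 or more (adjusted p = 0.0519) and without the 2 libraries of the GC trend (adjusted p = 0.0966). For lists that were not called, camera's direction turned in some settings, with the cause not tested. It weighs all members, so the medians given here need not change sign with it. It turned for the G2/M list with no filter (median 0.027), quantile scaling (0.009) and the GC correction with and without the block (-0.014), for the WNT list with no filter (0.075), for blood cell markers at a mean of 50 or more (-0.085), and for the Notch list with the GC correction with and without the block (0.113). Leaving out 1 library also turned camera's direction, not in every fit, for the G2/M list (medians 0.006 to 0.068), the WNT list (-0.175 to -0.027), the Notch list (-0.177 to -0.037), the 12q13-q15 list (-0.27 to -0.007), ribosomal protein genes (-0.103 to 0.194) and oxidative phosphorylation genes (-0.073 to 0.004), and the sign of MYCN (-0.148 to 0.193) and SFRP1 (-0.243 to 0.484). SFRP1 was also -0.337 with library weights.

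Of 92 called genes that the naming rule or the text singled out, 66 were called in all 6 fits without 1 library. The 25 that lost the call at least once included BCL2L11, CCNB2, CCND1, CDKN2D, CHGA, DISP1, DKK3, DUSP5, EBP, EGR2, ETV5, FDXR, H4C8, HERC6, INSM1, ISG20, ITGAM, LAMB1, LSS, MAP2, MFNG, MSMO1, SC5D and UQCRC1, most often without siGLI1 replicate 2 (24 genes) or siNT2 replicate 1 (20 genes), and NRARP was tested in only 5 of the fits. None of these 92 genes changed sign in any setting. Depth limits genes such as MAG and SOHLH1, whose siGLI1 means were under the floor of 3 reads.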

Other observations

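The test of the GC trend as the source of the calls was chosen after the result was seen, as were the GC correction and the removal of heptamer carriers as settings. The heptamer and the neighbouring-gene pattern below were noticed in these data and then tested on the same data, so their p-values are not those of independent tests. The genes of this paragraph were picked after their values were seen. Some genes outside the lists moved together with genes beside them on the chromosome. HOXD13, HOXD11 and HOXD10, homeobox genes of 1 cluster, fell by 1.33, 1.25 and 1.24 on the log2 scale (limma adjusted p = 0.0141, 0.0221 and 0.0245). TLE6, TLE2 and TLE5, genes of the Groucho family of transcriptional corepressors, fell by 1.67, 1.48 and 0.99 (adjusted p = 0.0276, 0.0364 and 0.0372). RUNX1, a transcription factor gene, went from 1209 ± 72.8 to 4250 ± 85.2 (SD, n = 3 per group; log2 fold change 1.82, adjusted p = 0.000277), and RCAN1, in the same run of genes, rose by 0.90 (adjusted p = 0.0124). DSPP, a gene of mineralised tissue beside DMP1, went from 2.44 ± 1.17, under the floor of 3 reads, to 27 ± 12 (SD, n = 3 per group; adjusted p = 0.0054). CD22, beside MAG, went from 35.71 ± 10.4 to 0.329 ± 0.57 and HAMP, in the same run, from 24.3 ± 4.43 to 2.02 ± 2.05 (SD, n = 3 per group), and both siGLI1 means are under the floor of 3 reads.

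Neighbouring genes changed the same way more often than random placement of the calls gave. Of 14794 neighbouring pairs, 331 were called in the same direction, against a mean of 178.7 and a highest value of 220 in 1000 random placements (permutation p = 0.001, the smallest they can give), and 100 in opposite directions. The tables argue against 3 technical sources as the whole cause, since the excess was there among pairs that do not overlap in the annotation (280, random highest 192), among those that also differ in the first 3 letters of their symbols, which leaves out most gene families (252, random highest 180), and after the GC correction with placement among genes in the same of 10 GC bins (1022, random highest 801). Transcripts that run past annotated gene ends, and antisense reads counted without strand, were not tested and stay open. A candidate explanation is that GLI1, or factors downstream of it, acts on stretches of chromosome that hold several genes, which these libraries alone do not test.

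Genes with the heptamer GCACCTC in the 3' UTR were lower in siGLI1 cells, by a mean of -0.162 with 1 copy and -0.331 with 2 or more, against 0.019 without it. These means are log2 fold changes, with extreme values capped, after adjustment for GC content and length of the 3' UTR and for the gene's mean expression. Its z of -11.42 was the most extreme of 15997 heptamers (highest absolute z in 1000 permutations 5.98), its reverse complement had -0.75, and no other heptamer of the same base composition that shared no hexamer with it passed an absolute z of 3.86, which argues against base composition or length as the source. Each siGLI1 library showed the shift against the siNT2 mean (-0.211, -0.205 and -0.18). Each siNT2 library was set against the other siNT2 libraries (-0.009 to 0.008), where a shift shared by that group cannot show. These values therefore do not tell in which group the genes moved. Genes with 2 or more copies differed from those with 1 by -0.169 (95% interval -0.278 to -0.06, permutation p = 0.00793). Pairing of a small RNA to this sequence predicts such a step. A candidate explanation is therefore that a strand of the GLI1 siRNA acted on other transcripts through its seed, though the siRNA sequences were not used here and a change in a natural microRNA was not tested. The longest GLI1 transcript carries 1 copy, as seed pairing by the strand that targets GLI1 needs. Of protein-coding transcripts of 3000 to 4000 bases, 24.3% carry the heptamer too, so this decides little. Seed pairing at this heptamer may account for part of the decreases in MMP15, ITGB3, UNG, HEYL and PKM. Direct pairing at copies in the annotated 3' UTR does not cover most lower genes. Of these, 21.1% (95% interval 18.6 to 23.6) carried the site against 8.7% of genes not called. With all carriers left out, camera at its preset correlation still called the GLI target list (adjusted p = 0.00559) and the G1/S list (6.8e-09) lower. With an estimated correlation neither full list was called (camera adjusted p = 0.209 for both). Sites in coding regions were not counted, nor were overlapping heptamers, of which CACCTCA had a z of -7.26. Indirect effects of lowered carriers on other genes were not tested, so a seed effect on non-carriers stays open. PTCH1, HHIP and FOXS1 carried 0 copies, while some carriers, such as TRIB3, EGLN3 and RUNX1, rose.

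Libraries of the same group were spread along GC content, and log2 fold changes correlated with GC content across genes (rank correlation -0.29, where genes are not independent replicates). The prediction was that a GC trend as the source of the calls would end most of them when removed, and 97.1% stayed called with the same sign. Removal also raises power, since in the simulation with a GC trend recovery at a fold of 2 went from 3.1% to 63.3%. A call could thus stay even where part of its change came from the trend, so the share does not settle how much the trend contributed. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many as 2376 called genes, and the highest of the others gave 0, with up to 3125 genes at an unadjusted p under 0.05 against 4943 in the real split. Every other split mixes the 2 groups on both sides, so the group difference adds to the spread and lowers the calls. The 0 therefore does not show how many calls chance would give. The split with 3125 put siNT2 replicate 2 and siGLI1 replicate 3, which stood at the same end of the GC trend, on the same side, and 10 splits are too few for a share under 0.05. The spread along GC content may hide smaller changes, since its removal gave 2431 genes higher and 2434 lower, and handling differences between the libraries were not recorded in the labels.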
